A study of Homo sapiens with 6 samples.

How the data were processed

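Gene expression was measured in HEK293 cells, a line derived from human embryonic kidney, on 6 single-colour NimbleGen expression arrays labelled with Cy3. Per the labels' protocols, cells were transfected with a control shRNA or an shRNA against SET8 for about 40 hours and then given control or Wnt3a conditioned medium for 7 hours before total RNA was extracted. The arrays fall into 3 groups of 2: control shRNA with control medium, control shRNA with Wnt3a medium, and SET8 shRNA with Wnt3a medium. SET8 shRNA with control medium was not analysed here, so the comparison of the Wnt3a response between the shRNAs, an interaction, could not be tested. Groups and replicate numbers were taken from the labels. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

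The authors deposited 1 intensity per probe set and array on a linear scale, summarised with RMA (robust multi-array average) per the submitters' processing notes; the version and settings of RMA were not given in the sources used here. The deposited series value table holds the same intensity values, with a largest difference of 0. Another deposited column, named as a standard error, lies on no stated scale and was not used. The array carries 45033 probe sets, of which 45031 have 3 probes, and a random control set of 1994 probes. Probe positions refer to genome build hg18 per the file headers. Gene names were updated through the Entrez gene ID with a RefSeq gene table: 38916 probe sets (86.4%) matched, the symbol of 11151 changed, and 2086 had no gene name. The array holds 23595 distinct symbols.

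Before the data were examined, the comparisons, the main model, 20 gene lists, the rule for the genes named and most alternatives were fixed. That plan assumed scanner signals, with background correction, quantile normalisation and probe summary to be done from them. The files hold values that the authors had already normalised and summarised, so those steps were not repeated, and the deposited intensities were taken to log2 with no offset. Other settings of background correction and probe summary, and a slide or scan block, were not run.

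Probe sets above the median of their array in at least 2 of the 6 arrays were tested: 23808 probe sets of 13070 genes, leaving 21225 untested. A linear model with 3 groups was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 3 residual and 4.32 prior degrees of freedom and a prior SD of 0.282 on the log2 scale. All groups share 1 estimate of the spread, because 2 arrays per group give too few degrees of freedom alone. Contrasts were Wnt3a minus control medium, SET8 minus control shRNA in Wnt3a medium, and SET8 shRNA with Wnt3a medium minus control shRNA with control medium. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets tested. Values are log2 intensities as mean ± SD of 2 arrays, and log2 fold changes carry the moderated standard error (SE). A 2 against 2 comparison of a single value cannot give an exact permutation p under 0.333, so no such test is reported.

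The genes named are, per contrast, the 12 highest and 12 lowest past the threshold, with 1 probe set per gene, a known symbol and no uncharacterised locus. Where fewer than 10 passed, the other places went by the smallest unadjusted p. The rule adds SETD8, 6 Wnt target genes always, and members of each list past the threshold or, with none, the 2 with the smallest p. For lists that were not called, not all members chosen in this way are given in the text. For 1 gene that this rule selects, the values are not reported here, with no other gene in its place; the list tests keep it. For several genes whose tested probe sets disagree, the values of further probe sets are given.

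Gene lists were tested on the probe set with the highest mean per gene. Camera compared each list with the other genes at an inter-gene correlation of 0.01, and again with an estimated correlation. Fry tested whether the genes of a list moved one way. Benjamini-Hochberg adjustment ran over the 20 lists of a contrast. The lists were Wnt feedback genes, other Wnt target genes, Wnt pathway components, H4K20 methylation and CRL4-Cdt2 genes, G1/S genes, G2/M genes, histone genes, p53 target genes, interferon response genes, immediate early genes, unfolded protein and amino acid response genes, heat shock genes, cholesterol synthesis genes, TGF-beta and BMP target genes, ribosome biogenesis genes, fibroblast genes, blood cell genes, epithelial line genes, reference genes and ribosomal protein genes. Probe sets in which both arrays of a group lay at least 1.5-fold above or below both arrays of the other were counted without a test. Because the Wnt3a and SET8 contrasts share the control shRNA arrays in Wnt3a medium, with opposite sign, the SET8 change of the 50 probe sets most raised by Wnt3a was set beside 50 simulated data sets with no SET8 effect, with independent noise and with noise correlated between same-numbered arrays as the replicate differences are. The latter noise, with no effects, also gave the number of probe sets expected at an unadjusted p under 0.05.

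The Wnt3a contrast was tested on simulated arrays of 23808 probe sets, 200 of them changed, in 20 runs. Without a replicate pattern, 9.1% of changes of 1 log2 unit, 61.4% of 1.5, 92.6% of 2 and 99.7% of 3 were recovered, with 7.58% false calls. With an added pattern that separates the replicates of the control shRNA arrays, 0%, 0.1%, 6.3% and 65.1% were recovered. This pattern made replicates differ more than in the data (SD 0.55 and 0.59), so these shares are likely too low. A shift of 0.9 in a list was called by camera in 20 of 20 runs in both settings. Other lists, with no shift added, were called in 1 of 380 tests without the pattern and in 6 of 380 with it. Probe sets were simulated as independent of each other, so these runs do not cover lists whose genes vary together.

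The median intensity was 198 to 221 per array, and the random control set lay at 25.3 to 28.6, or 4.66 to 4.84 on the log2 scale. The files used here carry no detection flags, so no probe set was called absent. Of the 23808 probe sets tested, 3 lay at or below the random control set in an array, and none did in both arrays of a group. Of all 45033, 4502 did in both arrays of a group, and differences of such values are bounds. Alternatives to normalisation, filter, spread estimate, samples in the fit, replicate number, threshold and left-out arrays were run, with others added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.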

Results

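Gene expression was profiled on 6 arrays of HEK293 cells to ask which genes Wnt3a changes and whether SET8, the enzyme that mono-methylates lysine 20 of histone H4, is needed for that change. Cells carried a control shRNA with control medium, a control shRNA with Wnt3a medium, or a SET8 shRNA with Wnt3a medium, with 2 arrays per group. Replicate arrays correlated across probe sets at 0.964 in control medium, 0.955 in Wnt3a medium and 0.978 with SET8 shRNA. Between replicates, 6.87%, 8.98% and 1.86% of the tested probe sets differed by more than 2-fold, in the same order of groups.

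The gene targeted by the shRNA, SETD8 (now KMT5A), was lower with SET8 shRNA in both arrays. On its brighter probe set (AY064546, chromosome 12, 122439555 to 122458998, hg18), log2 intensity was 10.89 ± 0.20 with control shRNA in control medium, 10.87 ± 0.47 in Wnt3a medium and 9.31 ± 0.48 with SET8 shRNA (SD, n = 2 each). The arrays read 11.03 and 10.75, then 11.20 and 10.53, then 8.97 and 9.65. The difference between the shRNAs in Wnt3a medium was -1.56 (SE 0.34), or 2.94-fold lower, with a limma adjusted p of 0.24 after Benjamini-Hochberg adjustment over all probe sets. In 3 models chosen after the data were seen, the limma adjusted p was 0.019 to 0.029. These held a term for the replicate pattern or for genomic span, called the length covariate below. In the other settings that keep both arrays of each shRNA in Wnt3a medium, it was 0.18 to 0.58. Adjusted over the list alone (H4K20 methylation and CRL4-Cdt2 genes), KMT5A fell, with an adjusted p of 0.031 from limma. A further probe set of the gene (NM_020382) gave -1.11 (SE 0.28), 2.16-fold lower, with an adjusted p of 0.33 from limma.

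**Figure D1:**
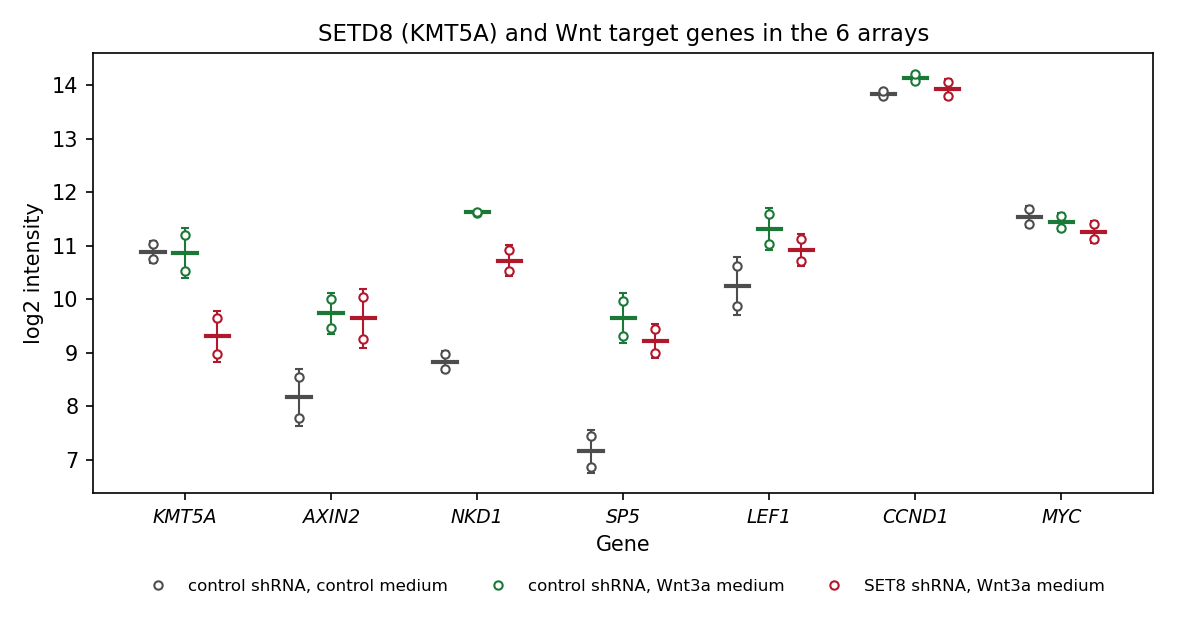
Log2 intensity of KMT5A (SETD8) and 6 Wnt target genes, 1 probe set per gene, in the 3 groups. Circles are the 2 arrays of a group, horizontal lines their mean and bars the SD. KMT5A lies at 8.97 and 9.65 in the SET8 shRNA arrays, below all 4 control shRNA arrays, and NKD1 lies at a mean of 8.84 in control medium and 11.62 in Wnt3a medium.

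The Wnt3a comparison asked which genes respond to 7 hours of Wnt3a medium. Feedback genes of the Wnt pathway were the group that stood highest. Of 16 measured Wnt feedback genes, 15 had higher values in Wnt3a medium and the median log2 fold change was 0.89. When adjusted over the list alone, 6 rose and 10 did not pass. These 6 were NKD1 (2.79, SE 0.25), an inhibitor of Wnt signalling that binds Dishevelled; DKK1 (2.56, SE 0.29), a secreted antagonist of the LRP5 and LRP6 co-receptors; SP5 (2.48, SE 0.34), a transcription factor; AXIN2 (1.56, SE 0.38), a scaffold of the beta-catenin destruction complex; LEF1 (1.07, SE 0.34), a partner of beta-catenin on DNA; and RNF43 (0.76, SE 0.23), a ubiquitin ligase that removes Wnt receptors. NKD1 went from 8.84 ± 0.19 to 11.62 ± 0.01 and DKK1 from 7.02 ± 0.52 to 9.59 ± 0.08 (SD, n = 2 each).

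Camera placed the Wnt feedback genes above other genes with an adjusted p of 2.8e-19 (Benjamini-Hochberg over 20 lists), and the adjusted p was 0.13 with an estimated correlation. The unadjusted p with the estimated correlation was 0.0065 and that of fry was 0.0049, a fry adjusted p of 0.098. The median was 0.77 between the arrays numbered 1 and 1.02 between those numbered 2. Other Wnt target genes had a median of 0.10 over 25 members, with a camera adjusted p of 0.22. Among them TBXT, the mesoderm transcription factor brachyury, rose when adjusted over the list alone (2.26, SE 0.29). CCND1 (0.30, SE 0.23) and MYC (-0.10, SE 0.25), 2 widely cited Wnt targets, differed by less than 2 SE. Same-numbered arrays of the 2 media deviated together (correlation 0.75), which the model does not remove, so the Wnt3a SEs are likely too wide. CCND1 read 13.79 and 13.89 in control medium and 14.08 and 14.20 in Wnt3a medium. For MYC the arrays read 11.68 and 11.41, then 11.56 and 11.32. MYC had 0.04 without control medium replicate 1 and 0.02 without Wnt3a medium replicate 2.

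No probe set passed an adjusted p of 0.05 over all 23808 in limma for Wnt3a, with a smallest adjusted p of 0.0575. At an unadjusted p under 0.05 there were 384 higher and 126 lower, 510 in all. Independent arrays with no effect would give 1190, but same-numbered arrays of the 2 media deviate together, and simulated noise with that correlation gave 130 (106 to 161), with probe sets taken as independent of each other. With an adjusted p under 0.1 the count was 2, with an intensity trend in the spread estimate 2, and with a filter at the 60th percentile 1. Models chosen after the data were seen gave 3 with the replicate numbers of the SET8 arrays crossed, 14 with an array term for the control shRNA arrays and 6 with a length covariate. The smallest adjusted p in limma belonged to LMO2, a transcription cofactor of blood progenitors (2.85, SE 0.22, adjusted p = 0.057 after Benjamini-Hochberg). Not past the threshold, and after LMO2, NKD1, DKK1, TBXT and SP5 by p on the higher side, were MAOB (1.74), ODAPH (1.52), SLC2A4 (1.62), CALCB (2.04), WNT11 (1.43), ZNF277 (1.36) and HVCN1 (1.58). A further probe set of ZNF277 gave 0.09. Most of these higher genes were bright enough to test only through arrays with Wnt3a medium, where they are high. These were LMO2, DKK1, TBXT, SP5, MAOB, ODAPH, SLC2A4, CALCB and HVCN1. ZNF277 was bright enough only through the SET8 shRNA arrays.

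On the lower side, none past the threshold, the smallest p belonged to COL1A2, a chain of type I collagen (-2.29, SE 0.40), the antioxidant enzyme SOD3 (-1.83), CD4 (-1.36), the chemokine CXCL12 (-1.95), PLAC9 (-1.15), MXRA8 (-1.07), H4C15 (-0.92), SPON2 (-1.34), SLC6A17 (-1.21), SLC43A3 (-1.06), EMILIN1 (-1.10) and ZNF211 (-1.01). Further probe sets of MXRA8 and ZNF211 reached 0.07 and 0.02. Of the fibroblast genes, a list of markers of another cell type, 4 of 12 members were bright enough to test, with a median of -0.46 and a camera adjusted p of 0.015, which was an adjusted p of 0.51 with an estimated correlation. In that list COL1A2 fell when adjusted over the list alone and 3 members did not pass. COL3A1 was at -0.85 (SE 0.34) and COL1A1 at 0.28 (SE 0.23). A further probe set of COL3A1 gave -0.04. The COL1A2 probe set was bright enough to test only through the control medium arrays. The same held for SOD3, CD4, CXCL12, SPON2, SLC6A17 and ZNF211. With no filter, a further probe set of COL1A2 was at -1.58 (SE 0.42). Camera also placed histone genes (median -0.13, adjusted p 0.043) and interferon response genes (median -0.24, adjusted p 0.028) below other genes, and with an estimated correlation these were an adjusted p of 0.51 and an adjusted p of 0.59. No histone or interferon gene passed when adjusted over the list alone.

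As a count with no test, 124 probe sets lay at least 1.5-fold higher and 29 lower in both Wnt3a arrays than in both control medium arrays, 153 in all. Splitting the same 4 arrays by replicate number gave 2658 and the crossed split gave 24. The count was 1182 without control medium replicate 1, 518 without control medium replicate 2, 902 without Wnt3a medium replicate 1 and 935 without Wnt3a medium replicate 2, since fewer arrays have to be separated.

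The SET8 comparison, with Wnt3a medium on both sides, asked what the SET8 shRNA changes. Interferon response genes were lower with SET8 shRNA: of 17 measured, 13 had lower values, with a median of -0.80. Of these, 7 fell and 10 did not pass when adjusted over the list alone. Among the 7 were IFIT1 (-2.11, SE 0.26), which binds foreign RNA, its partner IFIT3 (-1.68, SE 0.28), the transcription factor IRF7 (-1.47, SE 0.37), and IFI6 (-1.19, SE 0.32). The largest difference in OAS1, which makes an activator of RNase L, was -2.86 (SE 0.28, 7.25-fold lower), with 5 probe sets between -2.86 and -1.99 and an adjusted p of 0.089 from limma after Benjamini-Hochberg. IFIT1 went from 8.20 ± 0.24 to 6.09 ± 0.01 (SD, n = 2 each). Camera gave the list an adjusted p of 1.1e-06, and the adjusted p was 0.41 with an estimated correlation, with an unadjusted p of 0.045 and a fry p of 0.019, a fry adjusted p of 0.13. The median was -0.73 in SET8 replicate 1 and -1.11 in replicate 2, each against the mean of the Wnt3a arrays.

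**Figure D2:**
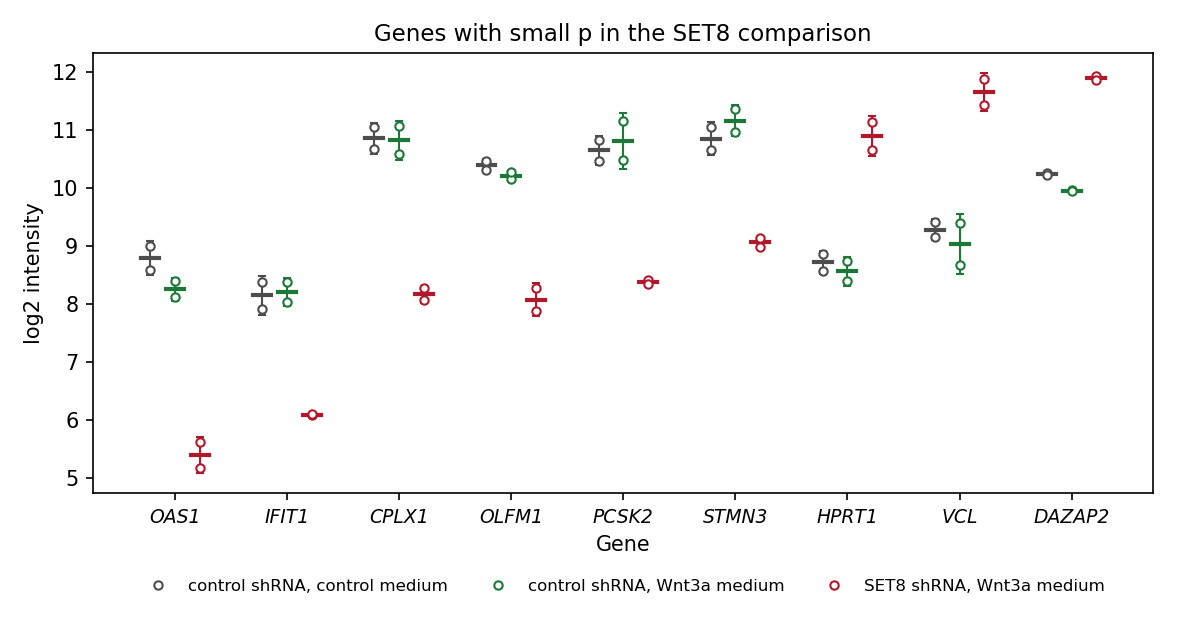
Log2 intensity of 9 genes with small p in the SET8 comparison, 1 probe set per gene, in the 3 groups. Circles are the 2 arrays of a group, horizontal lines their mean and bars the SD. OAS1, IFIT1, CPLX1, OLFM1, PCSK2 and STMN3 lie lower and HPRT1, VCL and DAZAP2 higher in both SET8 shRNA arrays than in all 4 control shRNA arrays, and OAS1 has a log2 fold change of -2.86.

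The lowest values, with none past the threshold over all probe sets, also included CPLX1, which binds the SNARE complex of synaptic vesicles (-2.65, SE 0.27), PCSK2, a prohormone convertase (-2.43, SE 0.30), AP3B2 (-2.45), OLFM1 (-2.14), STMN3 (-2.10), GOLGA7B (-1.95), TMEM198 (-1.89) and TMEM121B (-1.86). SSU72 (-2.38) and NDUFA8 (-2.39) were also low, and further probe sets of SSU72 reached 0.16. On the higher side stood VCL, the focal adhesion protein vinculin (2.62, SE 0.32), HPRT1, a purine salvage enzyme (2.33, SE 0.28), PRPS2 (2.22), TMEM19 (2.05), DAZAP2 (1.94), ATP6V1D (1.82), TDG (1.81), RPS6KA2 (1.81), CEND1 (1.78), IL27RA (1.72), GALC (1.69) and MKRN1 (1.67). A further probe set of TMEM19 gave 0.27. TDG, GALC and ATP6V1D were bright enough to test only through the SET8 shRNA arrays.

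In the SET8 comparison no probe set passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.0895. At an unadjusted p under 0.05, 894 were higher and 811 lower, 1705 in all. Independent arrays with no effect would give 1190, and the correlated noise gave 2058 (1967 to 2197). That noise takes the SET8 arrays as numbered, with replicate differences that correlate at -0.29 with those of the Wnt3a arrays. Exchanging these numbers would reverse the sign, and no such noise was run. The counts therefore do not decide whether there is an excess. With an adjusted p under 0.1 the count was 19 (3 higher, 16 lower), with the 4 arrays of this comparison alone 28, with an intensity trend 15 and with the filter at the 60th percentile 17. With the replicate number as a block it was 0, and in the models chosen after the data were seen it was 182 with crossed replicate numbers, 535 with the control-shRNA array term and 176 with the length covariate. It was also 28 without control medium replicate 1 and without control medium replicate 2, arrays that enter through the spread alone. As a count with no test, 405 probe sets lay at least 1.5-fold higher and 348 lower in both SET8 arrays, 753 in all, against 127 for the split by replicate number and 621 for the crossed split. This count was 3261 without Wnt3a medium replicate 1, 2354 without Wnt3a medium replicate 2, 2005 without SET8 shRNA replicate 1 and 1505 without SET8 shRNA replicate 2, since fewer arrays have to be separated.

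For the Wnt feedback genes no difference was called between the shRNAs. Their median was -0.07, with 10 of 16 lower, a camera adjusted p of 0.42 and a fry adjusted p of 0.73. It was -0.21 without SET8 shRNA replicate 2, and -0.21 with the length covariate (camera adjusted p 0.13), chosen after the data were seen. None of the 16 genes passed when adjusted over the list alone. KMT5A mRNA was lowered only in part, 2.94-fold and 2.16-fold on its probe sets, and SET8 protein was not measured on these arrays. NKD1 was at -0.90 (SE 0.25, adjusted p = 0.39 in limma after Benjamini-Hochberg), SP5 at -0.43 (SE 0.34), LEF1 at -0.39 (SE 0.34) and AXIN2 at -0.09 (SE 0.38). AXIN2 had 0.18 without Wnt3a medium replicate 1 and 0.30 without SET8 shRNA replicate 1. CCND1 (-0.21, SE 0.23) and MYC (-0.18, SE 0.25) differed by less than 2 SE. A further probe set of CCND1 gave 0.07.

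The 50 probe sets most raised by Wnt3a, of 44 genes, had a median of 1.35 in the Wnt3a comparison and 0.05 in the SET8 comparison, where 22 were lower. Both comparisons share the control shRNA arrays in Wnt3a medium with opposite sign, so a set chosen in this way lies below 0 by chance. Simulated arrays with no SET8 effect, with Wnt3a effects as fitted and with noise correlated between same-numbered arrays as in the data, gave a median of -0.13 (-0.25 to 0.01). Here too the noise takes the SET8 arrays as numbered. Independent noise gave -0.25 (-0.52 to -0.11), but alone it gives Wnt3a fold changes an SD of 0.32, above the observed 0.27, where the correlated noise gives 0.21. Across probe sets the fold changes of the comparisons correlated at -0.08, where correlated noise with no effects gave -0.34. The covariance was -0.009 against -0.029 from correlated noise, a difference of 0.021, and -0.051 from independent noise, where probe sets are not independent replicates. Splitting the shared pair leaves 1 array on each side: a set chosen with Wnt3a replicate 1 had a median of 0.85 against replicate 2, and a set chosen with replicate 2 had 0.64 against replicate 1. By construction these include 0.5 of the difference between the Wnt3a arrays, a term with medians of 0.65 and 0.38 in the sets, so they settle no SET8 change, and part of the values above may come from the shared arrays. The median was 0.21 without control medium replicate 2, -0.08 without Wnt3a medium replicate 1 and -0.32 without Wnt3a medium replicate 2.

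Some markers of other cell types and some reference genes passed in the SET8 comparison when adjusted over their list. Adjusted over the list alone, the haemoglobin genes HBA1 (-1.65, SE 0.38) and HBA2 (-1.12, SE 0.23) and the macrophage gene CD68 (-1.07, SE 0.26) fell, 3 of 5 blood cell genes measured (median -1.07, camera adjusted p 0.017, and an adjusted p of 0.41 with an estimated correlation). Epithelial line genes had a median of 0.49 over 9 members with a camera adjusted p of 0.015, an adjusted p of 0.41 with an estimated correlation, and none passed when adjusted over the list alone. Among 14 reference genes the median was -0.02 with a camera adjusted p of 0.64, but HPRT1 (2.33) and YWHAZ (1.23, SE 0.27) rose when adjusted over the list alone. Immediate early genes had a median of 0.17 over 22 members with a camera adjusted p of 0.015, an adjusted p of 0.54 with an estimated correlation. Of them FOS (1.37, SE 0.26), FOSB (1.12, SE 0.28) and NR4A1 (1.14, SE 0.24) rose when adjusted over the list alone.

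The other lists were not called in the SET8 comparison. Medians were 0.12 for G1/S genes, 0.20 for G2/M genes (camera adjusted p 0.062), 0.10 for histone genes, -0.21 for p53 target genes (camera adjusted p 0.062), 0.18 for unfolded protein and amino acid response genes, -0.04 for heat shock genes and 0 for cholesterol synthesis genes. They were -0.03 for TGF-beta and BMP target genes, -0.08 for ribosome biogenesis genes, -0.09 for ribosomal protein genes, 0.05 for Wnt pathway components, 0.04 for other Wnt target genes and -0.45 for the 4 fibroblast genes measured. The H4K20 methylation and CRL4-Cdt2 genes had a median of -0.05, with KMT5B, which adds further methyl groups at the same residue, at -0.99. None of the lists in these 3 sentences had a camera adjusted p under 0.05, and in them KMT5A alone passed when adjusted over the list alone. A median near 0 does not mean that single members stayed in place. Of the histone genes, H1-2 was at 1.77 (SE 0.41) and H4C8 at -0.70 (SE 0.22).

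**Figure D3:**
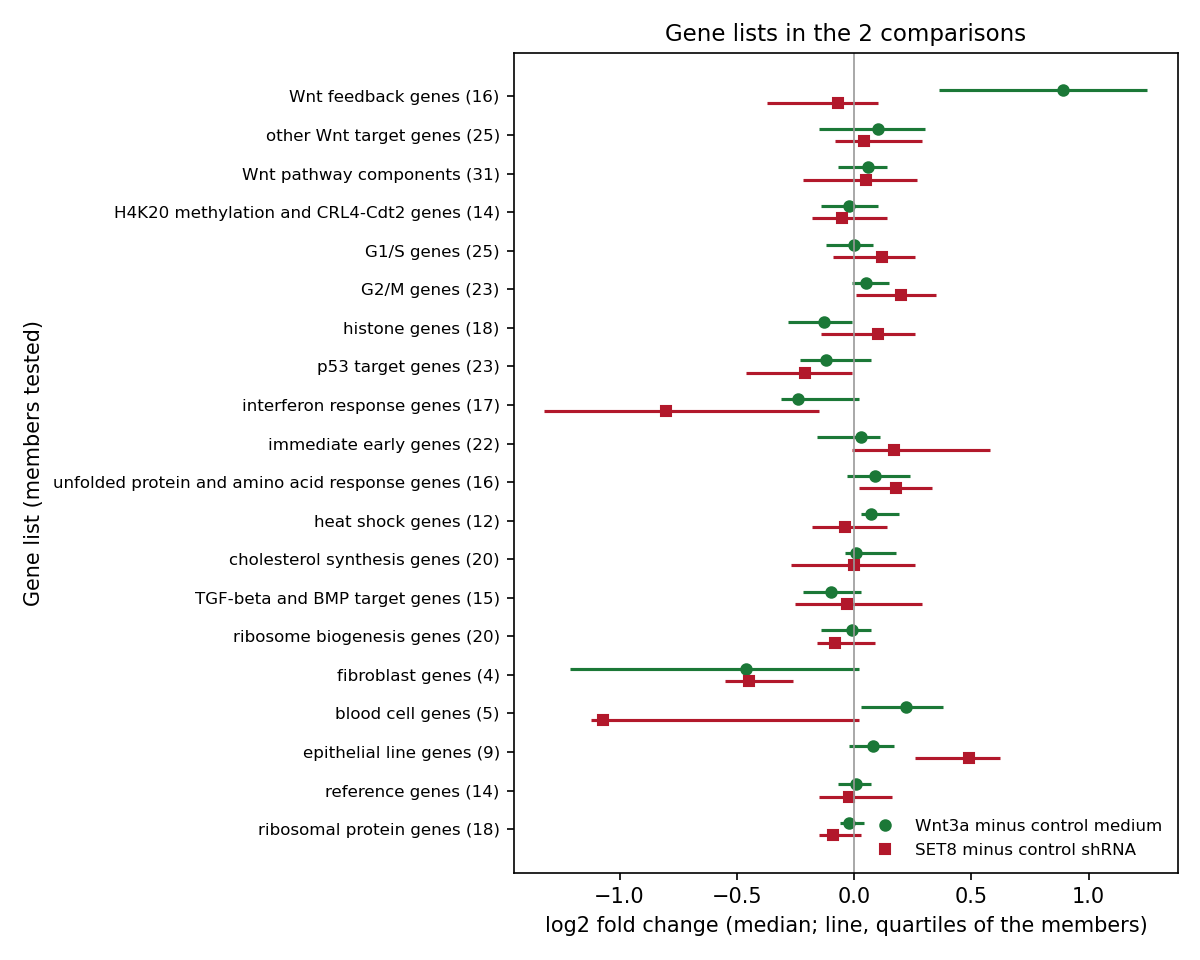
Median log2 fold change of the 20 gene lists in the Wnt3a comparison (circles) and the SET8 comparison (squares), with lines for the quartiles of the members and the number tested in brackets. Wnt feedback genes lie at 0.89 in the Wnt3a comparison and -0.07 in the SET8 comparison, and interferon response genes at -0.24 and -0.80.

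The last comparison set SET8 shRNA with Wnt3a medium against control shRNA with control medium, which combines both differences. Here 12 probe sets passed an adjusted p of 0.05 in limma, 6 higher and 6 lower. The genes that rose were CALCB, a calcitonin-related peptide (4.13, SE 0.32, adjusted p = 0.046 after Benjamini-Hochberg in limma), TBXT (3.01, SE 0.29), PIANP (2.98, SE 0.29), ZNF277 (2.21, SE 0.23) and LMO2 (2.08, SE 0.22). A further probe set of ZNF277 gave 0.95. CALCB, TBXT and LMO2 were bright enough to test only through arrays with Wnt3a medium, and ZNF277 only through the SET8 shRNA arrays. CALCB went from 5.70 ± 0.35 in control medium to 7.74 ± 0.47 in Wnt3a medium and 9.83 ± 0.29 with SET8 shRNA (SD, n = 2 each). The genes that fell were CPLX1 (-2.69, SE 0.27), OLFM1 (-2.31, SE 0.25), OAS1 (-2.27, SE 0.22) and TMEM121B (-2.17, SE 0.22).

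Other genes of small p in this comparison did not pass. Values on the higher side were SLC4A8 2.30, ATP6V1D 2.20, PRPS2 2.47, IL27RA 1.91, FAM131B 2.13, KISS1R 2.13 and SLC2A4 2.04, and on the lower side GOLGA7B -1.96, SSU72 -2.27, IFIT3 -2.40, NDUFA8 -2.36, TMEM198 -2.10, BSN -2.13, IFIT1 -2.06 and PCSK2 -2.27. Of the 3 tested probe sets of SSU72, 2 went the other way, up to 0.11. SLC4A8, ATP6V1D and KISS1R were bright enough to test only through the SET8 shRNA arrays, and IFIT3 only through the control medium arrays. Adjusted over the list alone, 5 Wnt feedback genes rose (median 0.82, camera adjusted p 1.4e-07, an adjusted p of 0.30 with an estimated correlation), with NKD1 at 1.89 and SP5 at 2.06, and 9 interferon response genes fell (median -1.02, camera adjusted p 4.8e-08, an adjusted p of 0.30 with an estimated correlation). Camera also called p53 target genes (median -0.36, adjusted p 0.006), fibroblast genes (median -0.73, adjusted p 0.0088) and epithelial line genes (median 0.66, adjusted p 0.0065). With an estimated correlation these had an adjusted p of 0.48, an adjusted p of 0.33 and an adjusted p of 0.30.

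The count of 12 was 22 without control medium replicate 1, 5 without control medium replicate 2, 230 without Wnt3a medium replicate 1 or without Wnt3a medium replicate 2, and 0 without SET8 shRNA replicate 1 or without SET8 shRNA replicate 2. It was also 0 with cyclic loess, with no filter and with the replicate number as a block, 31 with an intensity trend, 31 with the filter at the 60th percentile and 8 with median scaling. In settings chosen after the data were seen it was 792 with crossed replicate numbers, 1503 with the control-shRNA array term, 441 with the length covariate and 45 with an offset of 32. At an unadjusted p under 0.05 there were 1543 higher and 969 lower, 2512 in all. The correlated noise, which takes the SET8 arrays as numbered, gave 1787 (1692 to 1887).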

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

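Tests chosen only after the results were seen were the crossed pairing, the control-shRNA array term, the length covariate, the offset of 32 and the tracking of interferon response genes across settings. Background correction, probe summary and a slide or scan block were not run, because the deposited values were already summarised; the authors' value table is identical and gives no separate value. In each setting run for it, the Wnt feedback median stayed above 0 in the Wnt3a comparison, the interferon median stayed below 0 in the SET8 comparison, and KMT5A, not run for the mean over the probe sets of a gene, stayed lower with SET8 shRNA. Of the 23808 probe sets tested, 3 lay at or below the random control set in an array; without the filter, 9363 of 45033 did. Unless a sentence says otherwise, the cause was not tested.

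Counts past an adjusted p of 0.05 were 0 for Wnt3a, 0 for SET8 and 12 for the combined comparison. The combined count was 0 with cyclic loess, 0 with no filter and 45 with the offset. Fewer probe sets under the filter at the 60th percentile gave 1, 17 and 31, the intensity trend 2, 15 and 31, and an adjusted p under 0.1 gave 2, 19 and 156. The 4 arrays compared gave 28 for SET8 and 230 for the combined comparison. The counts with no test, 153 and 753, were 961 and 1339 with no filter, 40 and 448 at the 60th percentile, and 31 and 210 at 2-fold. The median SET8 change of the Wnt3a-raised set was -0.35 with no filter, -0.36 with the control-shRNA array term and 0.34 with the length covariate.

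The samples share only a replicate number. Deviations of same-numbered arrays correlated at 0.75 between the media and -0.29 between SET8 and either; with the replicate block the combined count was 0 and the other counts were 0. Crossing the numbers of the SET8 arrays gave 3, 182 and 792 calls. The array term for the control shRNA arrays gave 14, 535 and 1503 and the length covariate 6, 176 and 441. KMT5A passed under these 3 settings, at -1.56, -1.56 and -1.78.

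Leaving out each array in turn gave 0 to 0 Wnt3a calls, 0 to 28 SET8 calls, 0 to 230 combined calls, 153 to 1182 and 753 to 3261 for the counts with no test, 0.68 to 1.2 for the Wnt feedback median, -0.21 to -0.07 for it under SET8, -1.11 to -0.73 for interferon genes, -1.9 to -1.22 for KMT5A and -0.32 to 0.21 for the Wnt3a-raised set. An arm left with 1 array is assumed to vary like the other groups. SET8 calls were 28 without either control medium array, which leaves the 4 arrays compared.

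Over 17 settings, the 195 values of named genes gave 2779 results on the same side, 65 that lost their call, 388 that gained one and 14 of opposite sign. The last came only from leaving out an array, from 10 values that were not called. All values called in the main fit belong to the combined comparison. With cyclic loess, with no filter and with the replicate block, 9 lost their call, which was every one of them. Most results on the same side are thus values called in neither fit. Over the arrays left out, the Wnt3a change ran from -0.35 to 0.32 for KMT5A, -0.24 to 0.04 for MYC, -0.18 to 1.91 for HMMR, -0.05 to 0.69 for TBP, -0.75 to 0 for KMT5B, -0.71 to 0 for TGFBI, -0.18 to 0.93 for CD74 and -0.12 to 0.51 for RPS3. Leaving out an array of 1 medium unbalances the replicate pattern that the media share (correlation 0.75), which moves these Wnt3a values. TBP read 11.34 and 10.60 in control medium and 11.65 and 10.92 in Wnt3a medium. Between same-numbered arrays, KMT5A alone of these genes differed in direction. The SET8 change of AXIN2 ran from -0.48 to 0.3 and the combined change of CCND1 from -0.04 to 0.22.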

Other observations

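Tests chosen after the result they measure was seen were those on the correlation of SET8 replicates, on interferon response genes, on fibroblast genes set against the random control set and on stromal genes, and the lists of REST targets, early mesoderm and stromal genes were written after the leading genes had been seen.

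Fibroblast genes too dim for the main test were set beside the 4 members tested there. Over all probe sets with no filter, the 12 genes of the list fixed before the data were examined had a median Wnt3a log2 fold change of -0.99, with 10 lower and 6 of these at an unadjusted p under 0.05. None of 10000 random lists matched on mean expression lay lower (percentile 0; central range -0.25 to 0.29). POSTN and FAP lay below the random control set in both Wnt3a arrays, so their differences are only bounds, at least 2.55-fold and 1.61-fold lower against that set. With values put no lower than the random control set, the list median was -0.77, again below all 10000 lists. The 8 genes left without those 4 had a median of -1.23 with 7 lower, and -1.01 with values put no lower than the random control set, each below all 10000 random lists, which do not allow for genes that vary together. DCN was at -2.09 (SE 0.37), COL6A3 at -1.73 (SE 0.35) and THY1 at -1.35 (SE 0.38), and DCN went from a mean of 7.49 to 5.41, while the brighter members COL1A1 and FBLN1 were at 0.28 and -0.07. A wider list of 43 stromal genes, written once that result was known, had a median of -0.08 at percentile 2.19, but 10 of its genes were also on the fixed list. Without these 10, the other 33 had a median of -0.05 at percentile 8.3, inside the central range of -0.08 to 0.13, so the wider list adds no independent result. Among the 33, abundant SPARC was at 0.16, FN1 at -0.02 and COL6A2 at -0.13, while FBLN2 was at -1.94 (SE 0.64) and SFRP2 at 0.89 (SE 0.28). These are given as values, with no explanation weighed.

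The control shRNA arrays of both media differed by replicate number in the same probe sets, with a correlation of 0.75 between the replicate differences. A trend with transcript length between RNA preparations is a candidate explanation, for which genomic span, introns included, served as a stand-in. The replicate difference correlated with genomic span at a Spearman rho of 0.19 across probe sets, which are not independent replicates. Its median went from -0.118 in the fifth of probe sets with the shortest span to 0.129 in the longest. The SET8 arrays showed the trend with opposite sign, with a rho of -0.22 and medians from 0.115 to -0.13. A preparation shared by all 3 groups under 1 number is argued against, since SET8 replicate differences correlated with those of the control arrays at -0.29; one shared with the numbers of the SET8 arrays exchanged stays open. No biological explanation was tested, and the labels give none. In simulated arrays a pattern of this kind, set stronger than in the data, cut the recovered share of changes of 1.5 log2 units from 61.4% to 0.1%.

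Some neuronal genes stood low in the SET8 comparison, a theme picked from the low side with no neuronal list fixed beforehand. On the higher side CEND1, a gene of neuronal differentiation, was at 1.78. For the low genes REST, a repressor of neuronal genes outside neurons, gives a biological hypothesis. In a list of 46 REST targets that left out the genes already seen, 26 were measured, with a median SET8 log2 fold change of -0.47 and 20 lower, below all 10000 random lists matched on mean expression (percentile 0; central range -0.15 to 0.17). The same list had a median of 0.21 in the Wnt3a comparison (percentile 99.9, 21 of 26 higher), so part of the difference may come from the Wnt3a arrays that both comparisons share. Against control shRNA in control medium, which leaves these out, the median was -0.33 with 20 lower, below all 10000 random lists. The random lists do not allow for genes that vary together. Camera with an estimated correlation gave the list an unadjusted p of 0.0069 for SET8, 0.029 for Wnt3a and 0.026 for the combined comparison. Adjusted over the list alone, 9 fell, among them CHGA (-2.11), RUNDC3A (-1.89), MAPK11 (-1.87), NEFH (-1.56) and SYP (-1.33), while NEFL was at 0.64. A trend with genomic span between arrays is argued against as the whole cause, since the median was -0.48 with the length covariate. More REST activity with the SET8 shRNA may be the cause, as a hypothesis. REST mRNA itself was at 0.60 (SE 0.31), and at 0.21 (SE 0.31) against control shRNA in control medium, each under 2 SE, and a neuronal gene change of another origin stays open.

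Interferon response genes had a median of -0.80 in the SET8 comparison, with a camera adjusted p of 1.1e-06 and an adjusted p of 0.41 with an estimated correlation. A trend with genomic span is argued against by a median of -0.83 with the length covariate. A single deviating SET8 array is argued against by medians of -0.73 and -1.11 in the SET8 arrays, each against the mean of the Wnt3a arrays. For each pairing of a single SET8 array with a single Wnt3a array, the median lay between -1.22 and -0.66. Whether the SET8 shRNA lowered these genes or the control shRNA raised them cannot be told apart, because no untransfected array was analysed here; against control shRNA in control medium the median was -1.02. Lower interferon signalling with the SET8 shRNA may be the cause, as an untested hypothesis.

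TBXT and LMO2 among the highest Wnt3a values raised the hypothesis that early mesoderm genes rise as a class. In a list of 27 primitive streak and early mesoderm genes that left out those already seen, 16 were measured, with a median Wnt3a log2 fold change of 0.06 at percentile 65.5 of matched random lists (central range -0.11 to 0.17). The rule written before the test took a median inside the central range as no rise of the class, and this median lay inside it. A class rise too small to leave the central range is not excluded, so the test does not decide against one. The result covers the 16 genes measured, 10 higher and 6 lower, and does not decide for the leading genes left out.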
